A study of Canis lupus familiaris with 62 samples.

How the data were processed

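Total RNA of 62 canine meningiomas was sequenced, 1 library per tumour. Per the labels' protocols, specimens were surgical biopsies or post-mortem tissue, archived in paraffin between 2011 and 2022, and RNA was extracted from sections and sequenced as 150 nt Illumina pairs. The deposited file holds raw counts per gene. Per the file headers, the authors counted reads with featureCounts 2.0.4 over exons of Ensembl release 100 genes on CanFam3.1, primary alignments only, without regard to strand. The header shows the paired option without the option that counts fragments, so each read of a pair was counted, and between 61.0% and 88.9% of a library's counts above 0 were even. A count of 2 thus mostly stands for 1 fragment, and count-based precision is lower than the totals show. Per the submitters' processing notes, STAR and DESeq2 were used with canFam3; their versions are not given in the sources used here. Without strand, reads of overlapping genes on opposite strands cannot be told apart; none of the named genes overlaps another gene of the file. Counting of reads shared between near-identical genes is not given in more detail in the sources used here, so such genes are uncertain.

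The file has 30951 genes, no gene names and no column of another series. The name table at hand, of the assembly UU_Cfam_GSD_1.0, matched 0 of the identifiers. Therefore the 31 gene lists fixed before the data were examined, among them cell cycle genes and markers of other cell types, were not analysed, nor were the cell cycle score, its correlations with lists and chromosomes, its relation to survival, or the covariate built from brain cell markers. Cell types in the tissue were not measured. The rule for named genes asked for an adjusted p under 0.05, a mean log2 CPM of at least 1 and a difference of group medians of at least 0.5 with the sign of the fold change (neither minimum applied to survival, and no median or fold minimum to sex). It also asked for a gene symbol and took 10 genes per direction. Without symbols it was kept but for the symbol, and reduced to the 2 largest changes per direction with a mean log2 CPM of at least 1, and for survival to the 2 smallest p.

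Groups came from the treatment label, with Sx and RT read as surgery and radiotherapy. Replicates were numbered in accession order and pair nothing. Sample names begin with N or S and a number from 11 to 22, which the labels do not explain. All 21 S-named dogs had surgery, and 1 surgical dog (Sx replicate 1) has an N name. Counts of different libraries were compared in 1891 pairs over genes with counts, and the closest pair differed by a chi-square of 16.0 per gene, so no library appears more than once. Totals ran from 1967061 to 12063982 counts.

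Genes were filtered with filterByExpr by treatment group (18370 left) and scaled by TMM (factors from 0.557 to 1.24). Counts were fitted with edgeR 4.0.16 quasi-likelihood models in R 4.3.3, all 62 libraries in 1 fit with 6 treatment groups, sex and neuter status, and p-values were adjusted by Benjamini-Hochberg. The common dispersion was 0.627. The contrasts were the mean of Sx and SxRT against untreated, steroid against untreated, SxRT against Sx, female against male and intact against neutered. Survival was tested per gene by a Cox score test on log2 CPM (prior count 2) in surgical dogs, with dogs lost to follow-up censored and a chi-square p. These tests, the named-gene rule and the alternatives on normalization, filter, tool, covariates, samples, strata and censoring were chosen before the data were examined. Chromosome scores with a mean log2 CPM of at least 2 were fixed too, but only for a correlation with the cell cycle score. The interaction of sex and surgery, the use of these scores by group, by survival, by region and by chromosome pair, the principal components and library measures, and the further alternatives were chosen after the file was seen to hold no names. The scores were explored with a median over genes first, and the mean was kept because the fixed design named a mean.

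Chromosome scores were compared by 2-sided permutation of labels with 100000 resamples, or exactly where a group had under 10 dogs, with sex and neuter status permuted within treatment group and neuter status asked in males only. P-values were adjusted over 39 scores per comparison. Principal components used genes with a mean log2 CPM of at least 2. Windows of 2 Mb with at least 5 genes and bins of 10 Mb with at least 10 genes were used along chromosomes. Alternative fits used DESeq2 1.42.0 and limma 3.58.1 (voom with quality weights). Libraries past the widest and past the next widest gap on the first component (6 and 12 libraries) were left out in further fits. No library lay below the planned minimum depth, so that alternative changed nothing. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and lifelines 0.30.3 was used for the rest.

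The tests were tried on simulated counts drawn from the real means and library sizes, with 100 genes changed by 1 and 100 by 2 on the log2 scale. For surgery against untreated, 52 and 79 of them were recovered and 20 unchanged genes were called. For steroid the figures were 24, 53 and 6, for SxRT against Sx 16, 59 and 8, for sex 43, 75 and 5, and for neuter status 26, 56 and 8. Each gene was drawn independently and no library was made to stand apart, so these figures do not hold for the real libraries. Random splits of the real steroid and untreated samples called up to 280 genes. The Cox test was tried with simulated survival and censoring and a strong planted effect, on genes that varied among the surgical dogs. It gave an unadjusted p under 0.05 to 95.5% of changed and 5.94% of unchanged genes. The recorded survival, with 8 ends and 14 dogs censored, was not simulated, so neither share holds for it. On simulated scores 16 libraries lowered on chromosome 17 all scored under minus 0.2. Their recovery at the lower limit used in Results for a low score was not tried, so the check does not cover that limit.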

Results

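RNA was sequenced from 62 canine meningiomas, tumours of the membranes around the brain, each archived as formalin-fixed, paraffin-embedded tissue between 2011 and 2022. By their labels 27 dogs had no treatment, 7 had a steroid with or without an anti-epileptic drug, 3 had an anti-epileptic alone, 3 had radiotherapy alone (RT), 13 had surgery alone (Sx) and 9 had surgery with radiotherapy (SxRT). Of the dogs, 31 were female and 31 male, and 7 were intact, 6 of them male. The libraries held between 1967061 and 12063982 counts over 30951 genes, with a median of 4190135, and between 13085 and 18792 genes had at least 1 count. Genes of the mitochondrial chromosome took between 3.00% and 46.7% of a library's counts. The labels do not say whether the tissue was taken before or after a treatment. The series title speaks of a canine counterpart to an aggressive class of human meningioma, and the labels used here give no molecular class. Genes were therefore compared by treatment, sex, neuter status and survival, and expression was described along the chromosomes. The deposited file pairs no identifier with a gene name, so at most 2 genes per direction are named, by identifier, with positions on CanFam3.1.

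Tumours of dogs that had surgery carried 1171 genes at higher and 1907 at lower levels than tumours of untreated dogs (22 against 27 dogs, 18370 genes tested, edgeR quasi-likelihood test, adjusted p under 0.05). Among the called genes 346 were over 2-fold higher and 1429 over 2-fold lower. ENSCAFG00000031174, on chromosome 13 from 62526571 to 62528527, was higher by 4.08 on the log2 scale (SE 0.597, edgeR adjusted p 9.72e-06). Its log2 CPM was 3.94 ± 1.89 (SD, n = 22) in surgical and 0.62 ± 1.56 (SD, n = 27) in untreated tumours, and 22 of 22 surgical tumours lay above the untreated median. ENSCAFG00000004443, on chromosome 1 from 110087036 to 110092818, was higher by 4.03 (SE 0.512, edgeR adjusted p 4.22e-07) and lay above the untreated median in 21 of 22 tumours. ENSCAFG00000012964, on chromosome 38 from 21205107 to 21210451, was lower by 5.50 (SE 0.992, edgeR adjusted p 0.000198), with 2 of 22 surgical tumours above the untreated median. ENSCAFG00000002900, on chromosome 1 from 105900832 to 105907726, was lower by 4.84 (SE 0.757, edgeR adjusted p 3.32e-05), with 0 of 22 above that median. Over 16 alternative fits ENSCAFG00000012964 stood between -7.75 and -3.56 and lost its call in 3. ENSCAFG00000002900 stood between -6.60 and -2.74, ENSCAFG00000031174 between 2.23 and 6.10 and ENSCAFG00000004443 between 2.08 and 4.93, each losing its call in 1. With limma voom the split of the calls turned to 1604 higher and 1386 lower genes. Within the samples numbered 11 to 16 no gene was called by edgeR (2371 at an unadjusted p under 0.05), with these 4 genes at 2.23, 2.08, -7.75 and -6.60, and within those numbered 17 to 22 there were 71 calls. Of 17702 genes tested in both, 11718 had the same sign (r 0.51 across genes), and of the 2276 past an unadjusted p of 0.05 in the earlier numbers 1949 did.

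Some 2 Mb windows held more of the genes that were higher in surgical tumours than the rest of the genes tested. Of 984 windows, 9 passed for the higher genes (1-sided hypergeometric test, adjusted p under 0.05), and 0 passed for the lower genes (smallest adjusted p 0.0733). The windows of lower genes with the smallest p held fewer genes, such as 8 lower genes among 16 on chromosome 5 (1.67 expected, hypergeometric adjusted p 0.0733). Clustering of the higher genes only was thus not shown. The window with the smallest p, on chromosome 24 from 46077578 to 47672121, held 14 higher genes among 52, where 3.31 were expected (adjusted p 0.00290). Others lay on chromosomes 1, 6, 7, 25 and 31. By whole chromosome, chromosome 6 held 89 higher genes among 832 (52.9 expected, adjusted p 3.26e-05), chromosome 20 held 78 among 818 (52.0 expected, adjusted p 0.00406) and chromosome 25 held 41 among 385 (24.5 expected, adjusted p 0.0109). Chromosome 14 held 60 lower genes among 337 (35.1 expected, adjusted p 0.000927). Neighbouring genes vary together in these libraries, so these tests, which take genes as independent, give p-values that are too small.

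Surgical and untreated tumours also differed in measures of the library. The score on the first principal component, which carried 27.7% of the variance, was -44.8 ± 25.0 (SD, n = 22) in surgical and 14.6 ± 51.2 (SD, n = 27) in untreated tumours, and 21 of 22 surgical libraries lay below the untreated median (2-sided permutation test, p 2e-05, adjusted p 0.00012 over 12 tests). The exception, Sx replicate 1 at 36.8, is the 1 surgical dog whose sample name begins with N, and the others lay at -1.31 or below. The share of even values among counts up to 20 was 86.5% ± 3.46 in surgical and 91.2% ± 2.71 in untreated tumours, lower than the untreated median in 21 of 22 libraries (permutation p 1e-05, the smallest the permutations can give, adjusted p 0.00012). This share is high where both reads of a pair were counted for the same gene. Mitochondrial genes took 10.0% ± 4.01 of the counts in surgical and 14.4% ± 7.91 in untreated tumours, lower in 17 of 22 libraries (permutation p 0.0136, adjusted p 0.0407). Total counts were 5356585 ± 2070796 in surgical and 3951210 ± 1216060 in untreated tumours, higher in 17 of 22 libraries (permutation p 0.00451, adjusted p 0.0180). With the even share as a covariate 661 of the 3078 called genes were still called, and the median size of their change went from 1.33 to 1.10 on the log2 scale. With the first component 199 were, and it went to 0.41.

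**Figure D1:**
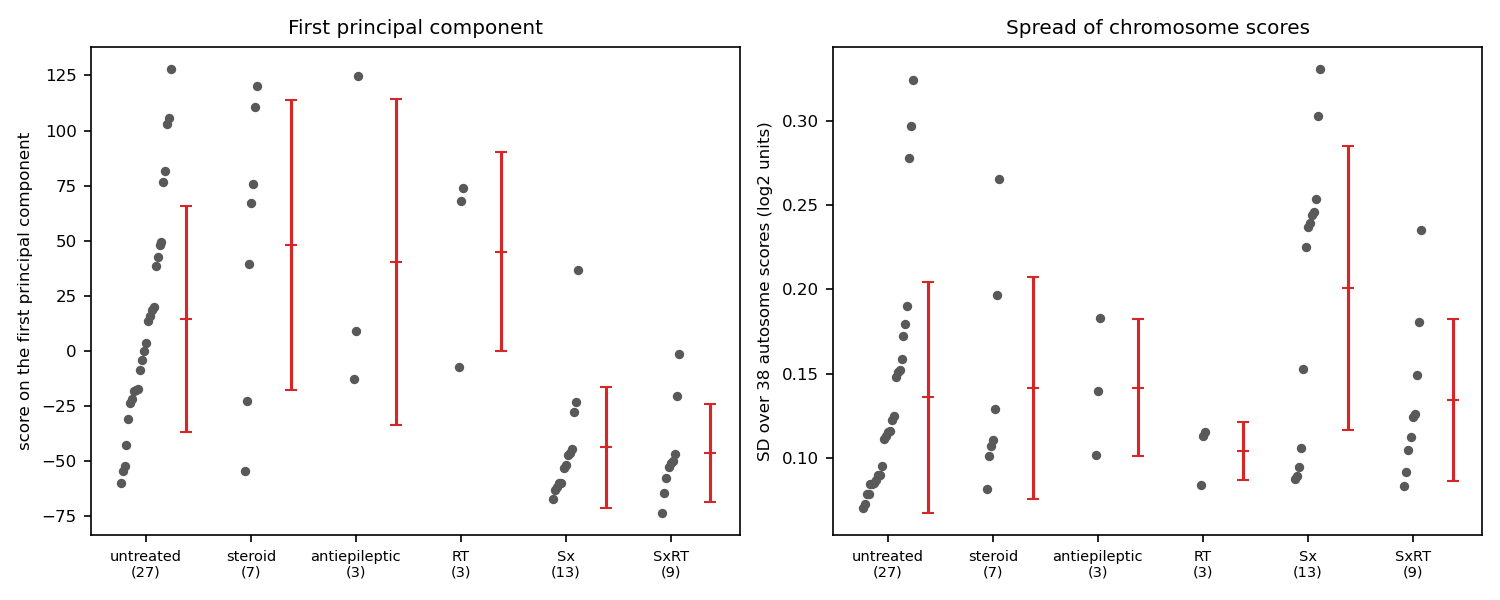
Score on the first principal component (left) and SD over the 38 autosome scores in log2 units (right) of each of the 62 libraries by treatment group, with the mean and SD in red. Surgical libraries had a first-component mean of -44.8, and untreated ones of 14.6.

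Tumours of the 7 dogs given a steroid carried 47 genes at higher levels than untreated tumours and 0 at lower levels (edgeR). At an unadjusted p under 0.05 there were 2016 genes. DESeq2 called 111 higher and 35 lower, and 33 of its calls were among the 47. Limma voom called 247 higher and 34 lower, but only 9 of its calls were among the 47. ENSCAFG00000008359, on chromosome 15 from 51915989 to 52138739, was higher by 4.11 on the log2 scale (SE 0.842, edgeR adjusted p 0.0119), with 5 of 7 steroid tumours above the untreated median. Its log2 CPM was 3.91 ± 3.54 (SD, n = 7) against 1.68 ± 1.58 (SD, n = 27). ENSCAFG00000018046, on chromosome 7 from 57914381 to 57947058, was higher by 3.88 (SE 0.853, edgeR adjusted p 0.0224), in 5 of 7 tumours. DESeq2 called both genes, at 4.13 and 3.88. With limma voom they stood at 2.57 and 2.47 and neither was called (limma voom adjusted p 0.0746 and 0.2275). On chromosome 13, 3 of the 12 genes between 20309872 and 22017988 were called higher, where 0.031 were expected (hypergeometric adjusted p 0.00345). The calls of the 2 named genes and of this window rest on single dogs. Without steroid replicate 5, whose library held 46.7% mitochondrial counts, 2 genes were called in all, fewer than the 3 of the window, and ENSCAFG00000008359 stood at 1.11 (edgeR adjusted p 0.874), and without replicate 7 ENSCAFG00000018046 stood at 0.26 (edgeR adjusted p 0.948). Without replicates 1, 2, 4 or 6 the calls were 84, 112, 88 and 142, and with only the 2 groups compared in the fit 1 gene was called, with these 2 genes at 3.70 and 3.65 (edgeR adjusted p 0.101 and 0.289).

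Tumours of the 9 dogs labelled with surgery and radiotherapy were set against those of the 13 with surgery alone, and the labels do not give the order of the treatments. ENSCAFG00000008999, on chromosome 33 from 1628105 to 1692058, was higher in SxRT by 3.23 on the log2 scale (SE 0.583, edgeR adjusted p 0.0142), and 8 of 9 tumours lay above the Sx median. Its log2 CPM was 8.16 ± 2.20 (SD, n = 9) against 5.84 ± 1.48 (SD, n = 13). ENSCAFG00000016488, on chromosome 20 from 48409045 to 48426669, was higher by 1.40 (SE 0.277, edgeR adjusted p 0.0425), again in 8 of 9 tumours. These 2 genes were the only ones edgeR called (939 at an unadjusted p under 0.05). DESeq2 called 19 higher and 21 lower, and limma voom 3 higher and 0 lower, which need not include them. Over 22 alternative fits ENSCAFG00000008999 stood between 2.44 and 3.45 and lost its call in 4. ENSCAFG00000016488 stood between 0.98 and 1.57 and lost its call in 10. Without SxRT replicates 6 or 7 edgeR called 0, with the 2 genes at 2.83 and 1.46 or 2.69 and 1.01, without replicates 3 or 5 it called 1, and without replicates 4, 8 or 9 it called 9, 12 and 15. With only these 2 groups in the fit 0 were called, at 3.29 and 1.34 (edgeR adjusted p 0.866 for both).

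Female tumours carried 9 genes at higher and 0 at lower levels than male tumours (31 against 31, edgeR, 1518 at an unadjusted p under 0.05). DESeq2 called 12 higher and 6 lower, and limma voom 5 higher and 1 lower, which need not be the same genes. Of the 9 edgeR calls, 5 lay on the X chromosome, where 0.348 were expected from the 711 X genes among the 18370 tested (1-sided Fisher's exact test, p 9.48e-06). ENSCAFG00000032071, on X from 16081392 to 16099142, was higher by 0.69 on the log2 scale (SE 0.129, edgeR adjusted p 0.0105), in 25 of 31 females against the male median. ENSCAFG00000014251, on X from 35759416 to 35789774, was higher by 0.56 (SE 0.105, edgeR adjusted p 0.0105), in 28 of 31. Its log2 CPM was 8.20 ± 0.41 (SD, n = 31) in females and 7.76 ± 0.35 (SD, n = 31) in males. Over 13 alternative fits ENSCAFG00000032071 stood between 0.51 and 0.71 and lost its call in 2. ENSCAFG00000014251 stood between 0.47 and 0.60 and lost its call in 1. The 4 called genes on other chromosomes and 1 of the 5 on X had a mean log2 CPM below 0. In neutered dogs alone 0 genes were called, with the 2 named genes at 0.71 and 0.52 (edgeR adjusted p 0.0909 and 0.101). The difference between surgical and untreated tumours was not found to differ between the sexes, with 0 of 15440 genes called for the interaction (edgeR, 551 at an unadjusted p under 0.05, no other tool was run).

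Intact dogs, 7 against 55 neutered dogs, carried 8 genes at higher and 0 at lower levels (edgeR, 1493 at an unadjusted p under 0.05). DESeq2 called 16 higher and 31 lower, and limma voom 8 higher and 5 lower, which need not be the same genes. ENSCAFG00000010955, on chromosome 27 from 19781557 to 19795078, was higher by 3.39 on the log2 scale (SE 0.667, edgeR adjusted p 0.0193), and ENSCAFG00000000223, on chromosome 10 from 1565244 to 1575982, by 2.47 (SE 0.510, edgeR adjusted p 0.0252). Each lay above the neutered median in 6 of 7 intact dogs. Over 20 alternative fits ENSCAFG00000010955 stood between 2.57 and 3.67 and lost its call in 6. ENSCAFG00000000223 stood between 1.73 and 2.69 and lost its call in 5. The log2 CPM of ENSCAFG00000000223 was 5.25 ± 1.91 (SD, n = 7) against 3.05 ± 1.43 (SD, n = 55). No gene was called in male dogs alone, where the 2 genes stood at 3.65 and 2.69 (edgeR adjusted p 0.605 and 0.473), nor without untreated replicate 9 (2.84 and 2.54), Sx replicate 9 (2.99 and 2.16) or SxRT replicate 4 (2.93 and 2.57), and without untreated replicate 23 the second stood at 1.73 and was not called. Without untreated replicate 1, SxRT replicate 7 or Sx replicate 11 the calls were 17, 13 and 23.

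Survival was asked about within the 22 surgical dogs, 8 with a recorded end and 14 lost to follow-up, because 16 of the 27 untreated dogs had a survival of 0. The labels give no unit. The median of the survival label was 86.5 in the 6 Sx and 276 in the 2 SxRT dogs with a recorded end. In the 7 Sx and 7 SxRT dogs lost to follow-up it was 80.0 and 499, which are times of follow-up. None of these medians estimates the survival of its group. Expression of 22 genes went with a higher hazard and of 0 genes with a lower one (Cox score test with a chi-square p, 18370 genes, adjusted p under 0.05, 1307 at an unadjusted p under 0.05). Of the 22, 14 had counts in 1 dog only and 20 in at most 3 dogs. ENSCAFG00000043643, on chromosome 4 from 45965277 to 45967577, was counted in 3 dogs with at most 10 counts. ENSCAFG00000047718, on chromosome 15 from 31447392 to 31544611, was counted in 2 dogs with at most 8 counts and had a log hazard ratio of 2.46 (SE 0.902) per log2 unit. No gene was called among the 16661 counted in at least as many of the surgical dogs as not (1108 at an unadjusted p under 0.05), nor with radiotherapy as a stratum (963).

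Expression varied by chromosome between tumours. The score of a chromosome was the mean over its genes of log2 CPM minus the gene's mean over the 62 libraries, less the library's median over the 38 autosomes (11486 autosomal genes). The scores of all 38 autosomes varied more between libraries than after genes were shuffled between chromosomes (1000 shuffles, adjusted p under 0.05 for each). Of the library-by-autosome scores 109 lay below -0.3 and 74 above 0.3, where shuffles gave 1.10 and 0.991 on average. The shuffles moved single genes, so neighbouring genes that vary together are enough to exceed them. They do not show that whole chromosomes varied. Chromosomes 1 and 25 passed too, though the scores of their first and second parts by position correlated with r 0.06 and -0.12. In 20 libraries no autosome lay beyond those limits, in 14 at least 5 did, and 1 library had 17. Between bins of 10 Mb, the median correlation over libraries was 0.345 for neighbouring bins (185 pairs), 0.318 for other bins under 4 apart (260 pairs), 0.244 for bins farther apart on the same chromosome (197 pairs), and 0.003 for bins of different chromosomes. Between 66.5% and 93.0% of an autosome's genes correlated positively with the mean of its others. The scores of an autosome's highly and lowly expressed genes correlated negatively on 13 of 38 autosomes, with the lowest r on chromosomes 7 (-0.445), 35 (-0.425) and 25 (-0.371), and those of its short and long genes did on 2, so not every autosome moved as a whole. The SD of the score over that of shuffles was highest for chromosomes 20 (5.44), 17 (5.33), 5 (4.47), 9 (4.40) and 3 (4.31).

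**Figure D2:**
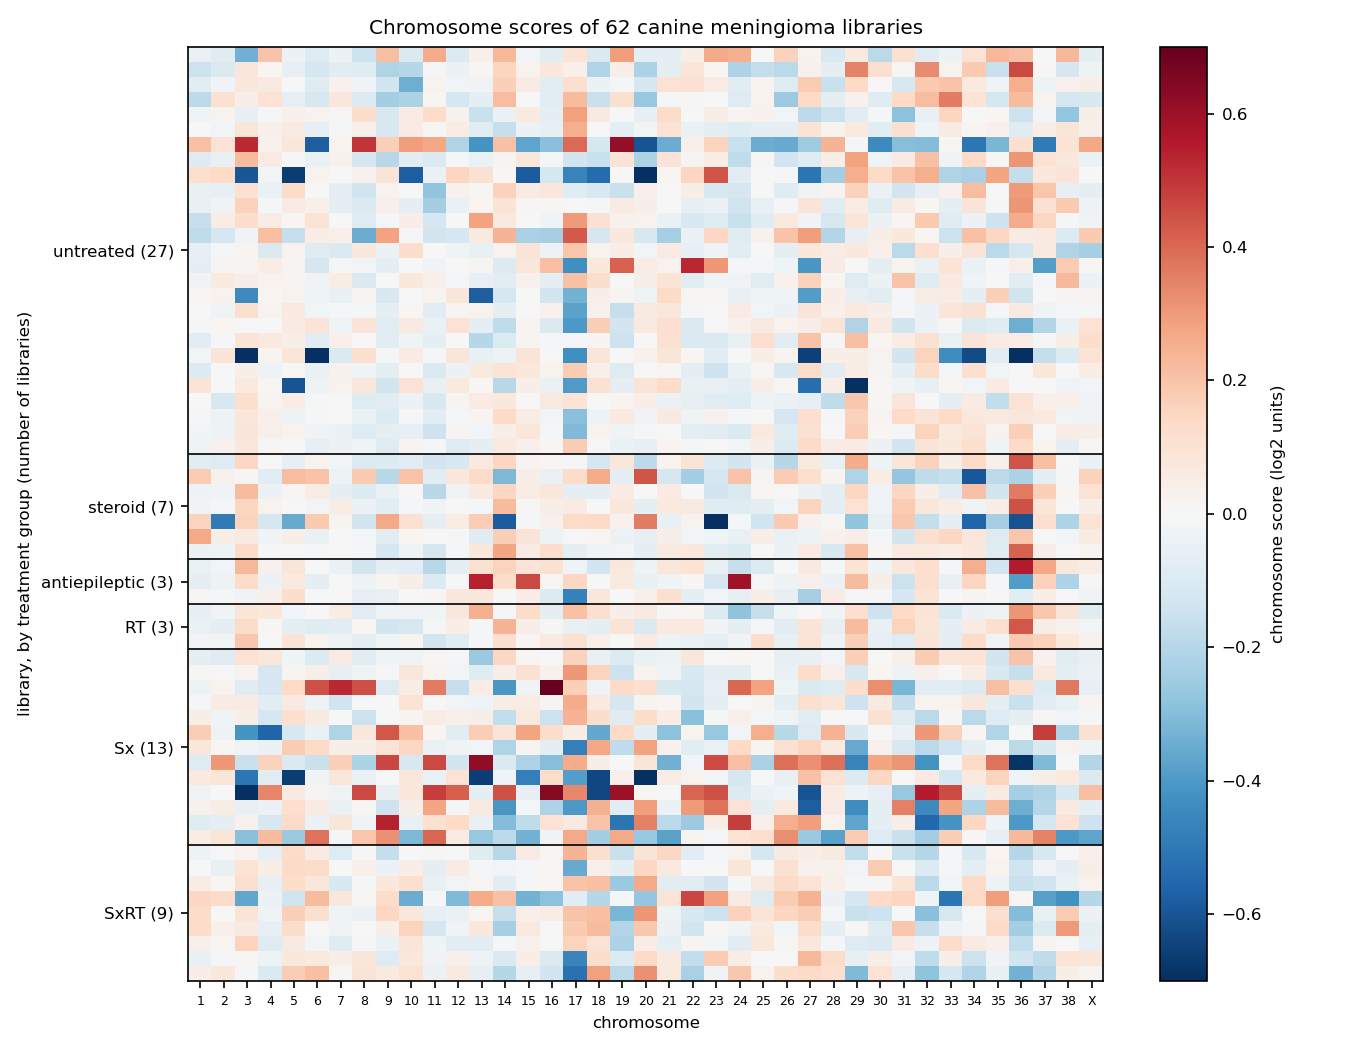
Chromosome scores in log2 units (colour) of 38 autosomes and X (columns) in each of 62 libraries (lines), ordered by treatment group. Blue columns in part of the libraries show chromosomes with a low mean, such as chromosome 17 with 15 libraries below -0.3.

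Chromosome 17 had the most libraries with a low score. Its scores ran from -0.523 to 0.428, with a gap between -0.293 and -0.135 that left 16 libraries below and 46 above. Below -0.3 lay 15 libraries, namely 8 of 27 untreated, 3 of 13 Sx, 3 of 9 SxRT, 1 of 3 antiepileptic, 0 of 7 steroid and 0 of 3 RT. Of its 370 genes 344 (93.0%) correlated positively over libraries with the mean of the others. The scores of its genes before and after position 38645857 correlated with r 0.70 among the 46 libraries above the gap (rho 0.719, permutation p 1e-05 for both, the smallest the permutations can give, r 0.717 without the 2 farthest) and with r 0.20 among the 16 below it (rho 0.265, permutation p 0.454 and 0.321). No difference in the score was detected between surgical and untreated tumours (0.0179 ± 0.299, n = 22, against -0.0252 ± 0.287, n = 27, permutation p 0.610). Spearman's rho of the score was 0.0111 with total counts, 0.0447 with the even share and -0.153 with the first component.

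**Figure D3:**
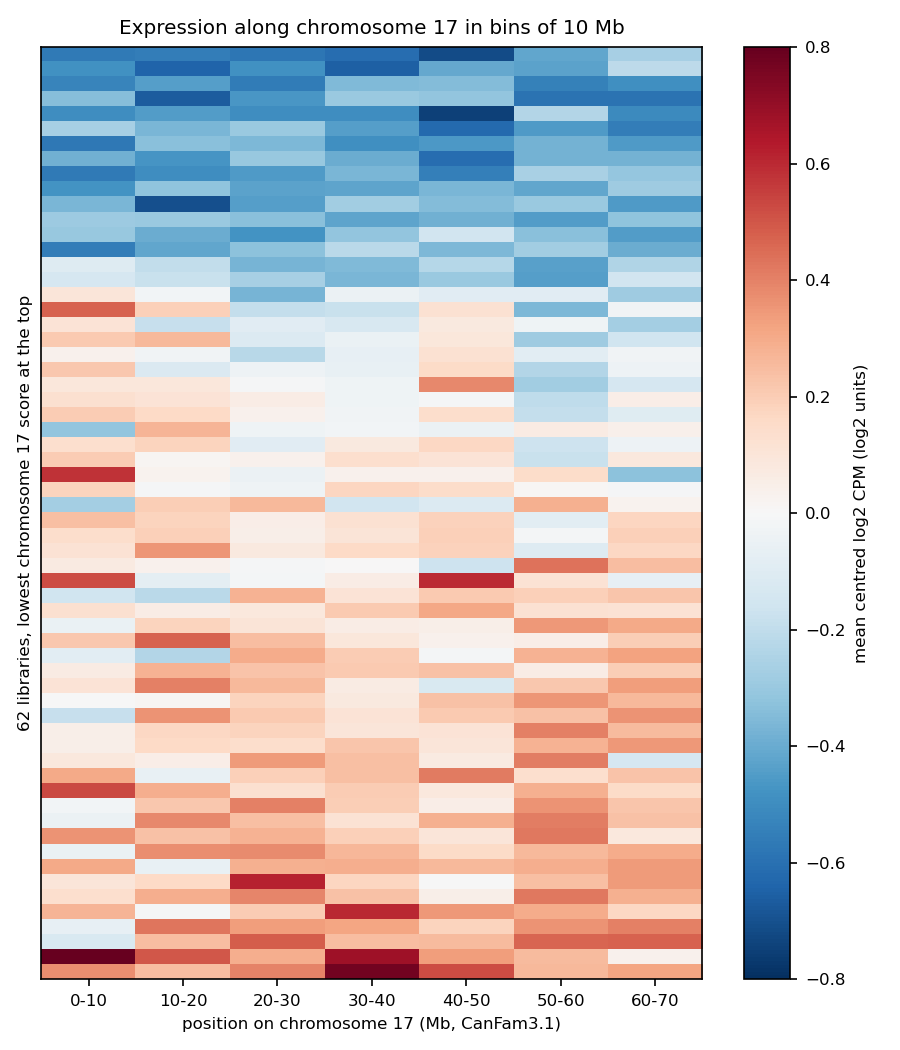
Mean centred log2 CPM (colour, log2 units) in bins of 10 Mb along chromosome 17 (columns) in each of 62 libraries (lines), sorted by the chromosome 17 score with the lowest at the top. The 16 libraries below the gap are low in the bins along the chromosome.

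Chromosomes 36, 3 and 27 were low in fewer libraries. Chromosome 36, with 103 genes, lay below -0.3 in 9 libraries, the lowest at -0.903, but above 0.3 in 10, and its score had a Spearman's rho of 0.713 with the first component. For chromosome 3, 8 libraries lay below -0.3 (4 untreated, 3 Sx and 1 SxRT), the lowest at -0.728. For chromosome 27, 7 did (5 untreated and 2 Sx), the lowest at -0.656. The score of chromosome 3 also went with the first component (Spearman's rho 0.655), while that of chromosome 27 had a rho of -0.035. The 2 parts of chromosome 3 correlated with r 0.84 over the 62 libraries (rho 0.473, permutation p 1e-05 and 0.00012, adjusted p 2e-05 and 0.00041 over 38 autosomes, r 0.774 without the 2 farthest). Those of chromosome 27 correlated with r 0.75 (rho 0.597, permutation p 1e-05 for both, adjusted p 2e-05 and 6e-05, r 0.693 without the 2 farthest). Over the 38 autosomes 32 had an adjusted p under 0.05 for r and 25 for rho, the 2 parts of chromosome 36 had r 0.40 (rho 0.380, permutation p 0.00118 and 0.00255, adjusted p 0.00179 and 0.00538, r 0.337 without the 2 farthest), and chromosome 12 had a negative r of -0.35.

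**Figure D4:**
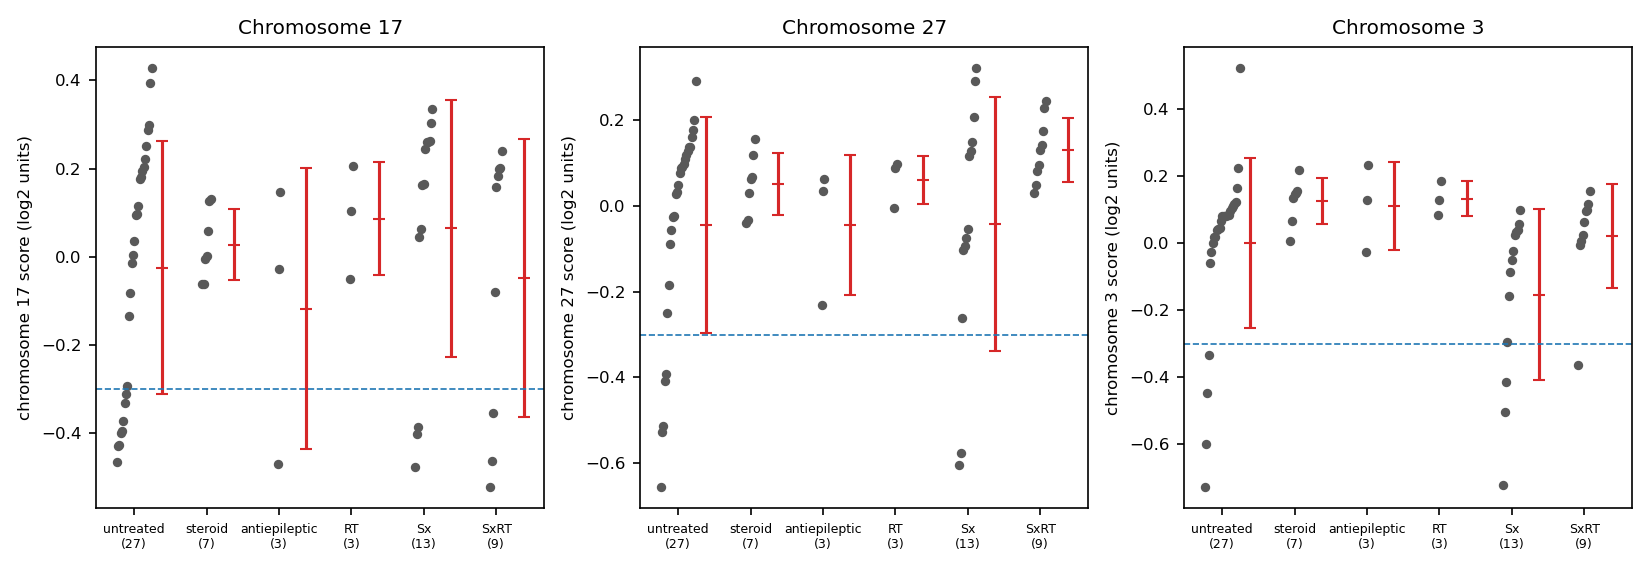
Scores of chromosomes 17, 27 and 3 in log2 units for each of the 62 libraries by treatment group, with the mean and SD in red and a dashed line at -0.3. Below the line lie 15, 7 and 8 libraries.

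Treatment groups differed in the scores of 7 of 39 chromosomes, all between surgical and untreated tumours (permutation test, adjusted p under 0.05). Chromosome 24 was higher in surgical tumours by 0.13 (0.07 ± 0.149 against -0.06 ± 0.089, above the untreated median in 19 of 22, adjusted p 0.00585) and chromosome 6 by 0.15 (18 of 22, adjusted p 0.0105). Chromosomes 26 and 1 were higher by 0.11 and 0.06 (18 and 16 of 22, adjusted p 0.0273 and 0.0432), though the highly and lowly expressed genes of chromosome 1 correlated with r -0.204 over libraries. That r was 0.0646 for chromosome 26, -0.016 for chromosome 29, and between 0.209 and 0.407 for chromosomes 6, 24, 32 and 36. Chromosome 36 was lower by 0.20 (19 of 22 below the untreated median, adjusted p 0.0354), chromosome 32 by 0.17 (18 of 22, adjusted p 0.0350) and chromosome 29 by 0.17 (19 of 22, adjusted p 0.0296). With the first component, or the even share and the total, regressed out, 0 of the 7 calls were left. Within the samples numbered 11 to 16 there were 5 calls, 3 of them among the 7, and within those numbered 17 to 22 there were 0. No chromosome passed for steroid, SxRT against Sx, sex or neuter status. The smallest adjusted p of each was 0.0620 (chromosome 23 in steroid tumours, lower in 7 of 7, exact p 0.00159), 0.215 (chromosome 11 in SxRT, lower in 9 of 9, exact p 0.00551), 0.607 (chromosome 37 in females, higher in 18 of 31, permutation p 0.0457) and 0.0568 (chromosome 31 in intact males, higher in 6 of 6, exact p 0.00146).

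The spread of the 38 autosome scores within a library ran from 0.0702 to 0.331 with a median of 0.119, where shuffles of single genes gave a median of 0.0613. It was 0.201 ± 0.084 (SD, n = 13) in Sx, 0.134 ± 0.048 (SD, n = 9) in SxRT and 0.136 ± 0.069 (SD, n = 27) in untreated tumours. Surgical tumours together had 0.173 ± 0.078 (SD, n = 22), above the untreated median in 14 of 22 (permutation p 0.0781, adjusted p 0.130 over 5 comparisons). SxRT lay below the Sx median in 9 of 9 libraries (exact permutation p 0.0466, adjusted p 0.130), which does not pass the correction. None of 45 items (39 chromosome scores, the spread and 5 principal components) passed a Cox permutation test of survival in the surgical dogs, and the spread had a log hazard ratio of 0.25 (SE 0.304) per SD, permutation p 0.427.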

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

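Tests of the surgical calls by sample name, even share, first component and name number, of the sex calls by their number on X, of the survival calls by random orders and by dogs counted, and every test on chromosome 17 were chosen only after the result was seen; the splits of the samples were planned.

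The 3078 genes called between surgical and untreated tumours are a pattern of the groupings as given: of 60 splits of the same samples, 1, the real one, gave as many, and the highest other gave 26, so chance can be excluded. The share of even counts was not checked against RNA quality, so adjusting for it cannot exclude RNA quality for any call. As a covariate the share left 661 genes called, the number in the sample name 2128 and the first principal component 199. None of them thus removes all the calls. For the remainder the share and the component stay open, because both differ between the groups (86.5% against 91.2%, and -44.8 against 14.6) and the median size of the change moved from 1.33 on the log2 scale to 1.10 with the share (quartiles 0.53 and 2.16, 99.9% with the same sign) and to 0.41 with the component (quartiles 0.17 and 0.92, 86.3% with the same sign), but the component is computed from the same expression values, so that a fall comes with it either way, and why calls ended with the share was not separated. The letter of the sample name cannot be told apart from surgery, since only 1 surgical dog has an N name. The labels do not explain the letter. If it marks the kind of specimen, that kind cannot be told apart from surgery either. The library of the N-named surgical dog, the 1 surgical library above the untreated median of the component, had a share of 86.6%. Biopsy against post-mortem tissue, the treatment itself and differences between the tumours that were operated on and those that were not are candidate explanations, none of them tested apart.

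The low scores of chromosome 17 in part of the tumours were weighed against 6 library measures, single genes and gene length. Cell types were not measured, the even share was not checked against RNA quality, and the components come from the same expression values. The regression therefore cannot decide on tissue mix or RNA quality, and both stay open. With 6 library measures regressed out (total, even share, mitochondrial share and the first 3 components), the scores of its 2 parts still correlated over the 62 libraries with r 0.96 (rho 0.944, permutation p 1e-05 for both, the smallest the permutations can give, r 0.950 without the 2 farthest), but 9 of the 15 libraries stayed below -0.3 (exact 95% binomial interval of the share 32.3% to 83.7%), so for their number these measures stay open. A few genes or gene length do not account for it, since 93.0% of its genes go with the others and the scores of its short and long genes correlated with r 0.80. Base composition was not tested, because no genome was used. A lower copy number of the chromosome in those tumours is a candidate explanation that no group of the design tests.

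The 22 survival calls can come from chance and from genes counted in few dogs. Counting the real order, 8 of 101 orders of survival over the dogs gave as many calls, and the highest other gave 64, so chance cannot be excluded. Of the 22 genes, 20 had counts in at most 3 dogs, for which the chi-square p is likely too small, and among genes counted in at least as many dogs as not 0 were called. Whether survival goes with expression of other genes stays open at 8 recorded ends.

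For the number of calls in the other comparisons, chance could not be excluded. Steroid calls numbered 47, with 16 of 60 splits as large and the highest other at 280. For SxRT against Sx the calls were 2, with 22 of 60 and the highest other at 34. For neuter status they were 8, with 10 of 60 and the highest other at 223. For sex they were 9, with 15 of 60 and the highest other at 136. Of these 9, however, 5 lay on X, and of the 60 splits 1, the real one, called as many X genes. The highest other called 4 X genes, among 136 calls in all. This count was chosen after the result was seen and the margin is small, so chance is not excluded for the X genes. Splits that call several times the real count point to a structure of the samples apart from these groups, single libraries that stand apart included, and its source was not tested.

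In small groups, 8 of 43 measures had a sample far from the others. This cannot be set against a chance rate of 1 in 20. The measures include genes called and chromosomes picked for their variation in these data, and several of the 8 share a library. Among steroid dogs replicate 5 stood apart with 46.7% mitochondrial counts (others 12.9% to 21.4%), 12063982 counts (others 2889519 to 5109817) and a chromosome 9 score of 0.2645 (others -0.192 to -0.0454). Among SxRT dogs replicate 4 had scores of -0.269 on chromosome 20 (others from 0.0542), -0.139 on chromosome 5 (others from 0.0609) and -0.363 on chromosome 3 (others from -0.0061). SxRT replicate 5 had ENSCAFG00000002900 at a log2 CPM of 4.07 (others up to 1.88). Among intact dogs untreated replicate 1 had 22.7% mitochondrial counts (others up to 11.8%).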

How the results depend on the processing

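Halved counts, mitochondrial genes left out, the covariates of even share and first component, the libraries left out, the genes counted in most dogs, and every alternative for chromosomes were chosen only after the data were seen; the rest was planned.

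The direction of the 12 named genes held in 213 of 214 alternative values, and 45 of these no longer passed the threshold. The exception was ENSCAFG00000018046 in steroid tumours, at -2.0015 without the 12 libraries past the next widest gap of the first component. Counts of called genes stayed within 1.5 times in 40 of 97 values. For surgery (3078) they did not in samples numbered 11 to 16 (0) and 17 to 22 (71), which hold fewer dogs, with the even share (734) or the first component (286) as a covariate, or without 12 libraries (1850); with RLE, no filter, DESeq2, voom, no other covariate, the compared groups only, S-named dogs only, halved counts or mitochondrial genes left out the count lay between 2914 and 4030.

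For steroid (47) the counts were 151 with no filter, 22 with the name number, 109 with no other covariate, 1 with the compared groups only, 281 with voom, 146 with DESeq2, 127 without 6 and 372 without 12 libraries, and 2 to 142 with each replicate left out. For SxRT against Sx (2) they were 1 with RLE, 8 with no filter, 1 with the name number, 11 with no other covariate, 0 with the compared groups only, 40 with DESeq2, 10 with the first component, 1 without 6 or 12 libraries and 0 to 15 with each replicate left out. For sex (9) they were 203 with no filter (153 higher and 50 lower), 0 in neutered dogs, 18 with DESeq2, 16 with the first component, and 24 and 17 without 6 and 12 libraries. For neuter status (8) they were 45 with no filter, 0 in males, 13 with voom, 47 with DESeq2, 5 with halved counts, 24 with the first component, 18 without 6 libraries and 0 to 23 with each intact dog left out. For survival (22) they were 0 with radiotherapy as a stratum, in S-named dogs, in all treated dogs by group, and among genes counted in most dogs, which tests fewer genes. Where fewer samples or genes do not show it, the cause was not tested.

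For chromosomes in surgical tumours (7) the counts were 4 with medians, 2 with the name number regressed out, 0 with even share and total or with the first component regressed out, 2 without 6 or 12 libraries, and 0 in samples numbered 17 to 22. With a floor of 4 on the mean log2 CPM 8 were called, but only 4 of these were among the 7. For neuter status (0) 1 chromosome was called with medians, a floor of 4 or the first component regressed out, and for steroid (0) 1 with even share and total regressed out. After correction over the comparisons of a setting, the spread passed in 0 of 40 values. Before it 10 had a p under 0.05, 5 for SxRT against Sx (-0.0667) and 5 for intact males (0.0628), between 0.0645 and 0.0836 for the latter, and the smallest corrected p of these was 0.0625. The counts of low libraries on chromosomes 17, 27 and 3 stayed within 1.5 times in 18 of 18 values. These values leave out the regression on 6 library measures described above, after which chromosome 17 was low in 9 libraries instead of 15.

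Not run were the alternatives for gene lists, cell cycle score and brain cell covariate, which need gene names, and the one on low totals, which removes no library. No paired analysis was possible because replicate numbers follow accession order and pair nothing. Totals between 1967061 and 12063982 counts limit what low genes can show: 699 of the 3078 surgical calls had a mean log2 CPM under 1.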

Other observations

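All tests of chromosome pairs and of the first component here were chosen only after the data were seen.

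Some chromosomes moved together across tumours. Of 703 pairs of autosomes, 106 had an adjusted p under 0.05 for Pearson's r (55 positive and 51 negative, Benjamini-Hochberg over the pairs, permutation tests). The scores of chromosomes 18 and 20 went together with r 0.79 (rho 0.847, permutation p 1e-05 for both, the smallest the permutations can give, adjusted p 0.00064), with r 0.848 without the 2 farthest libraries, 0.835 in untreated and 0.806 in surgical tumours, and 0.738 after total, even share and first component were regressed out. Chromosomes 9 and 21 went in opposite directions, with r -0.69 (rho -0.474, permutation p 1e-05 and 0.00019, adjusted p 0.00064), -0.625 without the 2 farthest, -0.628 in untreated and -0.757 in surgical tumours, and -0.692 after the same regression. Chromosomes 8 and 31 did so with r -0.61 (rho -0.496, permutation p 1e-05 and 3e-05, adjusted p 0.00064), -0.534 without the 2 farthest, -0.608 in untreated and -0.658 in surgical tumours, and -0.542 after the same regression. The relation of chromosomes 2 and 23, with r 0.64 (rho 0.229, permutation p 4e-05 and 0.0739, adjusted p 0.00117), rests on the 2 farthest libraries, since r was 0.252 without them. Other pairs among the 10 strongest had an r nearer 0 in untreated tumours or after the regression. Chromosomes 14 and 32 had r 0.65 (rho 0.614, permutation p 1e-05 for both, adjusted p 0.00064, r 0.623 without the 2 farthest), but 0.149 in untreated and 0.813 in surgical tumours. Chromosomes 26 and 32 had r -0.58 (rho -0.619, permutation p 1e-05 for both, adjusted p 0.00064, r -0.511 without the 2 farthest), but -0.0790 in untreated and -0.677 in surgical tumours. Chromosomes 18 and 19 had r -0.57 (rho -0.667, permutation p 1e-05 for both, adjusted p 0.00094, r -0.517 without the 2 farthest), but -0.200 in untreated and -0.780 in surgical tumours. Chromosomes 29 and 36 had r 0.61 (rho 0.698, permutation p 1e-05 for both, adjusted p 0.00064, r 0.645 without the 2 farthest), 0.314 in untreated and 0.827 in surgical tumours, and 0.280 after the regression. These differences between groups were not tested. Scores within a library are relative to its median chromosome, so a share of the negative relations comes with the construction.

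Along the first component, 6 libraries lay past the widest gap, between 81.4 and 102.8 (3 untreated, 2 steroid and 1 antiepileptic), and 12 past the next widest, between 49.5 and 67.2 (5 untreated, 4 steroid, 2 RT and 1 antiepileptic). No surgical library was among them. The component correlated with the even share with r 0.40 (rho 0.395, permutation p 0.00128 and 0.00146, adjusted p 0.0141 and 0.00803 over 11 relations, r 0.352 without the 2 farthest) and with the mitochondrial share with r 0.35 (rho 0.464, permutation p 0.00459 and 0.00017, adjusted p 0.0252 and 0.00187, r 0.486 without the 2 farthest). Within untreated tumours r was 0.218 and 0.229, and within surgical tumours 0.276 and 0.262. The spread of chromosome scores had r -0.304 with the component (rho -0.290, permutation p 0.0162 and 0.0229, adjusted p 0.0594 and 0.0838, r -0.308 without the 2 farthest), which does not pass the correction.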
